A study of Mus musculus with 9 samples.

How the data were processed

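RNA from livers of 2-month-old male mice, 8 or 9 per model, was combined into 3 independent pools for each of 3 models, and 5 micrograms of total RNA per pool were amplified and biotin-labelled, per the labels. The arrays were Affymetrix MOE430A, per the file headers. The authors deposited a linear signal intensity per probe set, in whole numbers with array minima of 25 or 26. How the authors summarised probes, corrected background and scaled the arrays is not given in the sources used here, so fold changes of dim probe sets depend on an unknown background step. Arrays had similar medians, 171 to 179, but their 2% trimmed means differed by 10.2%, above a tolerance of 5% set before the data were examined. Signals were therefore scaled to a common trimmed mean. The number of arrays limits the precision.

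Of 22690 probe sets 64 were controls. Of the other 22626, 20380 had 1 gene symbol, 691 had several and were not named, and 1555 had none listed. Symbols came from GEO's platform annotation and were checked by gene number against RefSeq names of GRCm38.p6, which changed 0 of them; no coordinates are printed because the sources used here name no genome build for the arrays. Values were log2(signal + 16). Probe sets in the upper 60% by mean log2 signal were kept, and the brightest probe set stood for its gene, leaving 8879 genes. Where a gene had several kept probe sets (2500 genes), opposite calls occurred for 1, Sdc4, in Cpr-low against Cpr-lox. The gene that encodes Cpr was not analysed here, so the labels of the models were not checked with it.

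All 9 arrays entered 1 limma 3.58.1 fit (R 4.3.3; lmFit, contrasts and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjusted p under 0.05), with a moderated F test over the models. Lists of genes, 51 of them fixed before the data were examined, were tested with camera at a preset correlation of 0.01 where at least 5 members were tested (48 lists), adjusted over the lists of a comparison; an estimated correlation and fry were alternatives. Markers of cholangiocytes, erythroid cells and adipocytes had too few tested members. Members are counted as rising or falling over all genes tested. Genes named were those fixed by rule before the data were examined: per comparison with Cpr-lox, the 8 largest rises and falls among called genes whose arrays do not overlap, up to 4 members with the smallest adjusted p from each list that was shifted or had at least 3 called members, and reference genes (Cyp2b10, Cyp3a11, Cyp7a1, Nr1i3, Nr0b2, Alas1, Cyb5a, Alb, and another that is not reported here); between the models, 5 and 2 in place of 8 and 4. The text names part of that set, and says below where a gene outside it is named. Sdc4, above, was named for its probe sets alone.

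Hybridization dates, scan dates and fluidics modules came from the run settings, per the file headers. The hybridization date was fitted as a block and the comparisons repeated within a date. Alternatives fixed before the data were examined changed the pseudocount (1, 64), the scaling, the filter (none, upper 40%), the intensity trend, the choice of probe set, the pool number or date as a block, and left out each pool. Keeping the deposited scaling and the fits within a date were chosen after seeing the data. On simulated data with the real genes' means and spreads, with 8879 genes and 100 genes changed at each fold in liver-Cpr-null, the fit recovered 87.4% of 1.5-fold and 98.3% of 2-fold changes over 20 simulations for liver-Cpr-null versus Cpr-lox, with 4.43% false calls. The simulated arrays held no date effects and no correlation between genes, so these rates need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).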

Results

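Gene expression was measured in the liver of 2-month-old male mice of 3 models on a mixed C57BL/6 and 129/Sv background. The models differ in Cpr, NADPH-cytochrome P450 reductase, the enzyme that passes electrons to the microsomal cytochrome P450 enzymes. The liver-Cpr-null model is named for a lack of Cpr in the liver, the Cpr-low model for a low level of it, and Cpr-lox is the control. RNA of 8 or 9 mice per model was combined into 3 pools per model, and each pool was hybridized to 1 Affymetrix MOE430A array, giving 9 arrays. The median deposited signal of an array lay between 171 and 179. Signals are means ± SD over n = 3 pools, and log2 fold changes are given ± SE on the log2(signal + 16) scale, which understates the changes of dim genes. Of 12393 genes with a named probe set 8879 were bright enough to be tested. Whether pools share mice is not given in the sources used here, so p-values measure only the spread between pools. Pools of a model correlated at 0.984 to 0.995 across tested genes, and arrays of different models at 0.969 to 0.988. Cpr-lox and Cpr-low pool 1 were hybridized on a first date and the others on a second, and only the Cpr-lox arrays were scanned on the first scan date, so scan date and control cannot be told apart. Every value against Cpr-lox with the hybridization date as a block therefore rests on Cpr-low pool 1. That array stood apart from the other Cpr-low pools, at -17.1 against -7.42 and -3.92 on the first principal component (35.5% of the variance of tested genes), and its deposited signals had the lowest trimmed mean, 349 in a range up to 384.

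The first comparison asked how the liver of liver-Cpr-null mice differed from that of Cpr-lox mice. The signal of Gstm3, a glutathione S-transferase, rose from 684 ± 62.8 to 13566 ± 2244, a log2 fold change of 4.27 ± 0.12 (adjusted p = 3.79e-10). Cyp2b10, a P450 induced through the nuclear receptor CAR, rose from 593 ± 275 to 9622 ± 1491 (log2 fold change 4.10 ± 0.27, adjusted p = 2.43e-06), and Cyp2c55 rose by 3.93 ± 0.18. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 2.28 ± 0.15, from 901 ± 226 to 4359.9 ± 515. Among the genes that fell were Hsd3b5 (-2.04 ± 0.36), a steroid dehydrogenase, Rad51b (-2.0 ± 0.16), Cyp17a1 (-1.71 ± 0.34) and Cyp7b1 (-1.70 ± 0.13), an oxysterol 7-alpha-hydroxylase. In all, 630 of 8879 genes differed at an adjusted p under 0.05, of which 325 rose and 305 fell, and 131 rose and 79 fell by at least 1.5-fold. With the hybridization date as a block the log2 fold changes were 4.51 ± 0.21 (adjusted p = 1.41e-06) for Gstm3, 3.87 ± 0.52 (adjusted p = 0.00535) for Cyp2b10, 2.07 ± 0.28 (adjusted p = 0.00642) for Cyp7a1 and -0.80 ± 0.52 (adjusted p = 0.429) for Hsd3b5. Cyp17a1 also lost its call there (-1.70, adjusted p = 0.193). A second, dimmer probe set of Rad51b had 0.04 (adjusted p = 0.893).

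**Figure D1:**
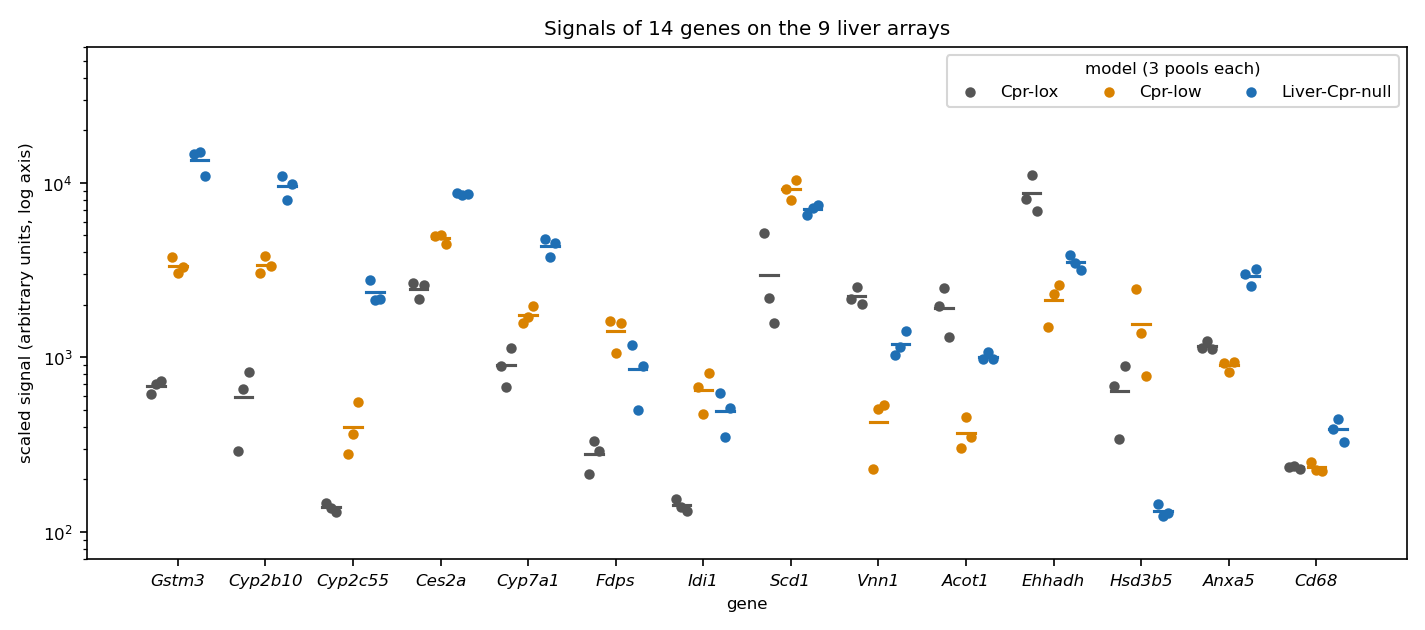
Scaled signal, on a log axis, of 14 genes on each of the 9 arrays; dots are pools, 3 per model, and bars their means. The mean signal of Gstm3 was 13566 in liver-Cpr-null and 684 in Cpr-lox, and that of Hsd3b5 133 and 640.3.

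Lists of drug-metabolism genes rose in liver-Cpr-null. Among targets of the nuclear receptors CAR and PXR, 20 rose and 0 fell of 25 tested members (20 and 1 adjusted over the list alone). The list averaged a log2 fold change of 1.24 (camera adjusted p = 4.74e-40, adjusted p = 0.00635 with an estimated correlation). Its members included Gstm2 (2.32 ± 0.10), the transporter Slco1a4 (1.82 ± 0.09) and the carboxylesterase Ces2a (1.81 ± 0.09). Of glutathione S-transferases, 12 rose and 0 fell of 21 tested members (12 and 1 adjusted over the list alone), with Gstm1 at 1.04 ± 0.07 and Gstm6 at 1.22 ± 0.10. Glutathione S-transferases averaged 0.74 (camera adjusted p = 1.04e-16, adjusted p = 0.010 with an estimated correlation). Of targets of the stress-responsive factor Nrf2, 11 rose and 0 fell of 17 tested members (12 and 1 adjusted over the list alone), among them Ugdh (1.42 ± 0.16) and the epoxide hydrolase Ephx1 (0.75 ± 0.07). Nrf2 targets averaged 0.83 (camera adjusted p = 5.82e-20, adjusted p = 0.010 with an estimated correlation). These lists overlap, since 7 CAR and PXR targets are glutathione S-transferases and 5 are Nrf2 targets. With the hybridization date as a block the averages were 1.13 (camera adjusted p = 1.03e-14) for CAR and PXR targets, 0.76 (camera adjusted p = 4.92e-07) for glutathione S-transferases and 0.74 (camera adjusted p = 2.54e-05) for Nrf2 targets, and Ugdh, at 1.01 ± 0.26 (adjusted p = 0.0805), lost its call.

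P450 families 1 to 4 moved both ways in liver-Cpr-null: 10 rose and 3 fell of 40 tested members (11 and 4 adjusted over the list alone). They averaged 0.28 (camera adjusted p = 4.85e-04, adjusted p = 0.138 with an estimated correlation) with a median of 0.02, and 0.19 (camera adjusted p = 0.488) with the date as a block. Cyp1a2 rose by 0.89 ± 0.11, Cyp2c29 by 0.77 ± 0.11 and Cyp3a11 by 0.36 ± 0.05. With the date as a block the calls were lost for Cyp1a2 (0.88, adjusted p = 0.0673) and Cyp3a11 (0.36, adjusted p = 0.0839).

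Sterol and lipid genes moved in both directions in liver-Cpr-null. In cholesterol biosynthesis, 9 rose and 0 fell of 17 tested members (10 and 0 adjusted over the list alone), with Idi1 at 1.66 ± 0.19, Hmgcs1 at 1.5 ± 0.24 and Cyp51, itself a P450, at 1.00 ± 0.16. Cholesterol biosynthesis averaged 0.65 (camera adjusted p = 3.11e-12, adjusted p = 0.0866 with an estimated correlation), and 0.78 (camera adjusted p = 2.54e-05) with the date as a block. Of genes of fatty acid oxidation and targets of the lipid-sensing receptor PPAR-alpha, 1 rose and 14 fell of 31 tested members (2 and 19 adjusted over the list alone), including the peroxisomal enzyme Ehhadh (-1.28 ± 0.19) and the ketone body enzyme Bdh1 (-1.10 ± 0.12). They averaged -0.36 (camera adjusted p = 1.97e-10, adjusted p = 0.195 with an estimated correlation), and -0.70 (camera adjusted p = 7.56e-23) with the date as a block. The sterol exporters Abcg5 (-0.98 ± 0.13) and Abcg8 (-0.80 ± 0.10) fell, as did Nr0b2 (-1.15 ± 0.19), a repressor of bile acid synthesis. The fatty acid transporter Cd36 rose by 1.33 ± 0.10 and lipoprotein lipase, Lpl, by 0.98 ± 0.09. With the date as a block the calls were lost for Hmgcs1 (1.62, adjusted p = 0.0937), Cyp51 (0.87, adjusted p = 0.147), Abcg5 (-1.06, adjusted p = 0.0551), Abcg8 (-0.72, adjusted p = 0.0732) and Nr0b2 (-1.01, adjusted p = 0.168), and Ehhadh had -1.99 ± 0.27. Of 3 dimmer probe sets of Hmgcs1, 1 had 0.86 (adjusted p = 0.0414). Alas1, the first enzyme of heme synthesis, had a log2 fold change of -0.37 ± 0.13 (adjusted p = 0.128), and -0.72 ± 0.21 (adjusted p = 0.112) with the date as a block. That of albumin, Alb, was -0.12 ± 0.05 (adjusted p = 0.240), and its sign was positive with quantile normalization and with the date as a block.

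Markers of Kupffer cells, the resident liver macrophages, were higher in liver-Cpr-null: 11 rose and 0 fell of 14 tested members (11 and 0 adjusted over the list alone). Cd5l rose by 0.94 ± 0.14, Lyz2, also a neutrophil marker, by 0.81 ± 0.12 and Cd68 by 0.68 ± 0.09. Kupffer cell markers averaged 0.47 (camera adjusted p = 2.40e-15, adjusted p = 0.0861 with an estimated correlation). Of endothelial, lymphocyte and neutrophil markers 0 of 10, 1 of 9 and 1 of 10 were called, and these lists averaged 0.03, 0.01 and 0.03 with medians of -0.01, -0.02 and -0.05. Of stellate cell and matrix markers, 1 rose and 0 fell of 17 tested members (1 and 0 adjusted over the list alone), averaging 0.08 (camera adjusted p = 0.0444, adjusted p = 0.449 with an estimated correlation) with a median of 0.02. That call was lost with the date as a block, 0.13 (camera adjusted p = 0.230), and without 1 of several pools (adjusted p = 0.0645 without Cpr-lox pool 2, 0.192 without Cpr-lox pool 3, 0.0553 without Cpr-low pool 3, 0.0911 without liver-Cpr-null pool 1 and 0.103 without liver-Cpr-null pool 2), and the average was 0.12 without Cpr-lox pool 1 and 0.03 without Cpr-lox pool 3. Of hepatocyte markers, 0 rose and 5 fell of 16 tested members (0 and 5 adjusted over the list alone), averaging -0.14 (camera adjusted p = 0.00510, adjusted p = 0.0744 with an estimated correlation), a call lost without Cpr-lox pool 3 (adjusted p = 0.0556). Of cytoskeleton and injury genes, 8 rose and 0 fell of 19 tested members (12 and 0 adjusted over the list alone), with Actg1 at 1.35 ± 0.13, the phospholipid-binding Anxa5 at 1.31 ± 0.09 and the keratin Krt8 at 0.91 ± 0.13. Cytoskeleton and injury genes averaged 0.49 (camera adjusted p = 3.11e-12, adjusted p = 0.0609 with an estimated correlation). With the date as a block the averages were 0.48 (camera adjusted p = 3.36e-05) for Kupffer cell markers, -0.22 (camera adjusted p = 0.00121) for hepatocyte markers and 0.52 (camera adjusted p = 1.85e-04) for cytoskeleton and injury genes, and the calls were lost for Cd5l (0.97, adjusted p = 0.0853), Lyz2 (0.47, adjusted p = 0.212) and Krt8 (0.83, adjusted p = 0.121). Of a list of commonly used control genes, 1 rose and 0 fell of 12 tested members (1 and 0 adjusted over the list alone), averaging 0.13 (camera adjusted p = 0.00128, adjusted p = 0.0609 with an estimated correlation), and 0.11 (camera adjusted p = 0.374) with the date as a block. The 3' to 5' signal ratio of the beta-actin control probe sets was 1.97, 1.99 and 1.62 on the liver-Cpr-null arrays and 1.17 to 1.43 on the others, and that of the Gapdh control probe sets 2.34, 2.48 and 2.43 on the liver-Cpr-null arrays, 2.72, 2.51 and 2.36 on the Cpr-low arrays and 2.79, 2.60 and 2.71 on the Cpr-lox arrays.

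Pericentral genes, expressed around the central vein, rose in liver-Cpr-null (9 rose and 0 fell of 18 tested members (11 and 1 adjusted over the list alone)), among them the ammonium transporter Rhbg (1.25 ± 0.17). Pericentral genes averaged 0.49 (camera adjusted p = 7.09e-11, adjusted p = 0.0387 with an estimated correlation), and 0.57 (camera adjusted p = 2.54e-05) with the date as a block. Of periportal genes, 0 rose and 3 fell of 14 tested members (0 and 5 adjusted over the list alone), with Hal, the histidine-degrading enzyme, at -0.93 ± 0.13. Periportal genes averaged -0.19 (camera adjusted p = 0.0236, adjusted p = 0.307 with an estimated correlation), and -0.28 (camera adjusted p = 0.00167) with the date as a block, where Rhbg had 1.25 ± 0.33 (adjusted p = 0.0853), losing its call with a larger SE. Without Cpr-lox pool 3 periportal genes averaged -0.11 (camera adjusted p = 0.644). In Cpr-low pericentral genes averaged 0.32 (camera adjusted p = 0.00329, adjusted p = 0.221 with an estimated correlation). Periportal genes averaged -0.12 there (camera adjusted p = 0.0252, adjusted p = 0.367 with an estimated correlation). That periportal call was lost without 1 pool (adjusted p = 0.552 without Cpr-lox pool 3 and 0.152 without Cpr-low pool 1). Of 48 lists 31 were shifted in liver-Cpr-null, and 4 with an estimated correlation, those of CAR and PXR targets, Nrf2 targets, glutathione S-transferases and pericentral genes. Regrouping the liver-Cpr-null and Cpr-lox arrays without regard to model still shifted up to 21 lists at the preset correlation. With the hybridization date as a block 149 genes were called, 52 rising and 97 falling, and 105 of the 630 kept their call, 629 keeping their sign. The count was 401 without Cpr-lox pool 2 and 348 without liver-Cpr-null pool 1. With median scaling 306 genes rose and 148 fell, and with the deposited scaling 335 rose and 204 fell.

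The second comparison asked how Cpr-low liver differed from Cpr-lox liver. Cyp2b10 rose to 3399.8 ± 373 (log2 fold change 2.61 ± 0.27, adjusted p = 1.30e-04) and Gstm3 to 3358 ± 354 (2.27 ± 0.12). Rises were also found for the sterol synthesis genes Fdps (2.27 ± 0.26), Idi1 (2.05 ± 0.19) and Msmo1 (2.04 ± 0.30), and for the fatty acid desaturase Scd1 (1.80 ± 0.30). Among the genes that fell were Rad51b (-2.56 ± 0.16) and the PPAR-alpha targets Vnn1 (-2.44 ± 0.24), Acot1 (-2.30 ± 0.19), Cyp4a14 (-2.06 ± 0.43) and Ehhadh (-2.03 ± 0.19). Serum amyloid A1, Saa1, had a log2 fold change of -2.0 ± 0.43 from a variable Cpr-lox signal of 6496 ± 5219, a call lost with the date as a block, at -1.93 ± 0.65 (adjusted p = 0.0739), and without 1 Cpr-low pool (adjusted p = 0.0551 without Cpr-low pool 1 and 0.0666 without Cpr-low pool 2). Cyp4a14 had -1.31 without Cpr-low pool 1 and lost its call without Cpr-lox pool 2 (adjusted p = 0.0526). Dimmer probe sets gave 0.14 (adjusted p = 0.537) for Rad51b, 1.31 (adjusted p = 0.00138) for Gstm3, 1.14 (adjusted p = 0.00167) for Scd1 and, for 1 of 2 of Cyp2b10, 1.72 (adjusted p = 5.08e-05). In all 514 genes differed, of which 205 rose and 309 fell, and 88 rose and 90 fell by at least 1.5-fold. Within the first hybridization date, where 1 Cpr-low array stood against 3 Cpr-lox arrays and was assumed to vary like them, the log2 fold changes were 2.46 ± 0.41 for Cyp2b10, 2.43 ± 0.13 for Gstm3, 2.49 ± 0.19 for Fdps, -3.20 ± 0.14 for Vnn1 and -3.57 ± 0.11 for Cyp4a14. Of the genes named in this comparison so far, Scd1, at 1.81 ± 0.46 (adjusted p = 0.0527), and Saa1, at -1.93 ± 0.63 (adjusted p = 0.107), did not pass there.

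**Figure D2:**
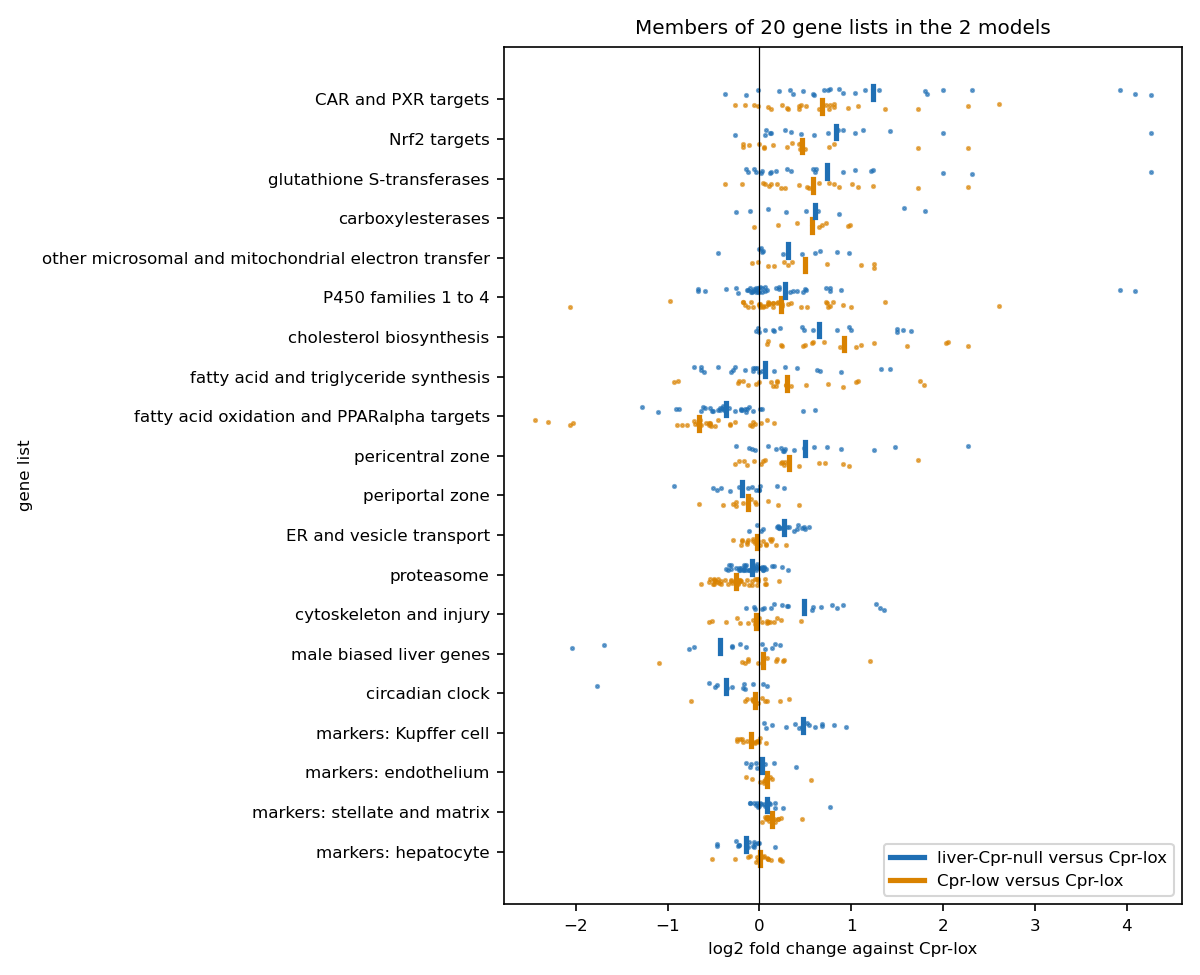
Log2 fold changes against Cpr-lox, on a linear axis, of the tested members of 20 gene lists in liver-Cpr-null and in Cpr-low; dots are genes and bars the list means. The CAR and PXR targets averaged 1.24 in liver-Cpr-null and 0.68 in Cpr-low, and the Kupffer cell markers 0.47 and -0.10.

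Fatty acid oxidation genes and PPAR-alpha targets fell in Cpr-low: 0 rose and 20 fell of 31 tested members (0 and 24 adjusted over the list alone). They averaged -0.66 (camera adjusted p = 7.02e-25, adjusted p = 0.109 with an estimated correlation). In cholesterol biosynthesis, 13 rose and 0 fell of 17 tested members (15 and 0 adjusted over the list alone), among them Sqle (1.25 ± 0.19) and Dhcr7 (1.11 ± 0.14). The list averaged 0.93 (camera adjusted p = 8.07e-17, adjusted p = 0.107 with an estimated correlation). Of CAR and PXR targets, 16 rose and 0 fell of 25 tested members (19 and 0 adjusted over the list alone), and they averaged 0.68 (camera adjusted p = 8.07e-17, adjusted p = 0.0355 with an estimated correlation). Of glutathione S-transferases, 12 rose and 1 fell of 21 tested members (15 and 2 adjusted over the list alone), with Gsta3 at 1.24 ± 0.10, and they averaged 0.59 (camera adjusted p = 2.32e-13, adjusted p = 0.0355 with an estimated correlation). Nrf2 targets averaged 0.46 (camera adjusted p = 1.22e-06, adjusted p = 0.107 with an estimated correlation), with 9 rising and 0 falling of 17 tested members. Of electron-transfer genes other than Cpr, which include Sqle and Dhcr7, 5 rose and 0 fell of 11 tested members (8 and 0 adjusted over the list alone). Cyb5b rose by 1.25 ± 0.09 and the cytochrome b5 reductase Cyb5r3 by 0.73 ± 0.08, and cytochrome b5, Cyb5a, had 0.16 ± 0.06 (adjusted p = 0.137). Of 3 dimmer probe sets of Cyb5r3, 1 had 0.07 (adjusted p = 0.679). Electron-transfer genes averaged 0.49 (camera adjusted p = 3.31e-07, adjusted p = 0.0760 with an estimated correlation). Of carboxylesterases, 6 rose and 0 fell of 9 tested members (8 and 0 adjusted over the list alone), and they averaged 0.57 (camera adjusted p = 3.31e-07, adjusted p = 0.113 with an estimated correlation). In liver-Cpr-null electron-transfer genes also rose, by 0.31 (camera adjusted p = 7.99e-06, adjusted p = 0.0609 with an estimated correlation). Carboxylesterases rose there by 0.60 (camera adjusted p = 1.06e-06, adjusted p = 0.0856 with an estimated correlation). Of genes of fatty acid and triglyceride synthesis, 7 rose and 2 fell of 23 tested members (10 and 2 adjusted over the list alone), with Acly at 0.75 ± 0.08 and the elongase Elovl5 at -0.93 ± 0.11, and they averaged 0.31 (camera adjusted p = 0.0322, adjusted p = 0.356 with an estimated correlation), a call lost without 1 pool (adjusted p = 0.117 without Cpr-lox pool 1 and 0.313 without Cpr-low pool 3). Of Kupffer cell markers, 0 rose and 0 fell of 14 tested members (0 and 0 adjusted over the list alone), and they averaged -0.10 (camera adjusted p = 0.0176, adjusted p = 0.639 with an estimated correlation), a call also lost without 1 pool (adjusted p = 0.0531 without Cpr-lox pool 3, 0.0607 without Cpr-low pool 1 and 0.0517 without Cpr-low pool 3). Stellate cell and matrix markers averaged 0.14 (camera adjusted p = 0.0202, adjusted p = 0.493 with an estimated correlation), with 0 of 17 called. Exocrine pancreas markers averaged 0.22 (camera adjusted p = 0.0322, adjusted p = 0.366 with an estimated correlation), with 1 of 6 called. Without Cpr-lox pool 3 both calls were lost (adjusted p = 0.101 and 0.0671). Endothelial, lymphocyte, neutrophil and hepatocyte markers did not pass.

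Within the first hybridization date Cpr-low pool 1 alone stood against 3 Cpr-lox arrays and was assumed to vary like them. The averages in Cpr-low were there -0.89 for fatty acid oxidation, 1.01 for cholesterol biosynthesis, 0.60 for CAR and PXR targets and 0.60 for glutathione S-transferases. They were 0.48 for electron-transfer genes, 0.56 for carboxylesterases, 0.34 for fatty acid synthesis, which did not pass (camera adjusted p = 0.462), and -0.09 for Kupffer cell markers. The fit with the date as a block gives the same averages from the same array, so neither shows how Cpr-low pools vary. Of 48 lists 20 were shifted in Cpr-low, and 2 with an estimated correlation, CAR and PXR targets and glutathione S-transferases. Regrouping the Cpr-low and Cpr-lox arrays without regard to model still shifted up to 19 lists at the preset correlation. The count of genes was 274 without Cpr-lox pool 2, 442 within the first date and 1090 with the date as a block, 624 rising and 466 falling, where 369 of the 514 kept their call. With median scaling 104 genes rose and 250 fell.

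The third comparison asked where liver-Cpr-null and Cpr-low differed. Liver-Cpr-null was higher for Cyp2c55 (2.56 ± 0.18), Gstm3 (2.0 ± 0.12), asparagine synthetase, Asns (1.91 ± 0.22), Actg1 (1.90 ± 0.13), Anxa5 (1.68 ± 0.09), Cyp2b10 (1.49 ± 0.27) and Cyp7a1 (1.30 ± 0.15). Of the other 2 probe sets of Cyp2b10, 1 had 1.37 (adjusted p = 0.0889). It was lower for the steroid dehydrogenases Hsd3b5 (-3.24 ± 0.36) and Hsd3b2 (-1.81 ± 0.22), for Asic5 (-1.94 ± 0.38) and for the glycogen-targeting subunit Ppp1r3c (-1.54 ± 0.17). Cyp3a11 had 0.06 ± 0.05 (adjusted p = 0.479). In all 748 genes differed, 414 higher and 334 lower in liver-Cpr-null. Within the second hybridization date the log2 fold changes were 2.08 ± 0.13 (adjusted p = 0.00125) for Gstm3, 1.83 ± 0.15 (adjusted p = 0.00164) for Actg1, -2.83 ± 0.20 (adjusted p = 0.00164) for Hsd3b5 and 1.23 ± 0.12 (adjusted p = 0.00267) for Cyp7a1.

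Of Kupffer cell markers, 10 were higher and 0 were lower of 14 tested members (13 and 0 adjusted over the list alone) in liver-Cpr-null than in Cpr-low, and they averaged 0.57 (camera adjusted p = 2.07e-17, adjusted p = 0.109 with an estimated correlation). Hepatocyte markers averaged -0.15 (camera adjusted p = 0.00727, adjusted p = 0.109 with an estimated correlation), with 5 of 16 lower. Exocrine pancreas markers averaged -0.33 (camera adjusted p = 0.0404, adjusted p = 0.344 with an estimated correlation), with 1 of 6 lower. Without Cpr-low pool 3 both calls were lost (adjusted p = 0.0567 for each). Stellate, endothelial, lymphocyte and neutrophil markers did not pass. Of CAR and PXR targets, 13 were higher and 0 were lower of 25 tested members (15 and 0 adjusted over the list alone), and they averaged 0.56 (camera adjusted p = 5.88e-16, adjusted p = 0.0805 with an estimated correlation). Of fatty acid oxidation genes, 8 were higher and 3 were lower of 31 tested members (12 and 3 adjusted over the list alone), with Acot1 at 1.43 ± 0.19, and they averaged 0.30 (camera adjusted p = 5.98e-06, adjusted p = 0.413 with an estimated correlation), and 0.19 without Cpr-low pool 1. Of cholesterol biosynthesis genes, 0 were higher and 3 were lower of 17 tested members (0 and 4 adjusted over the list alone), and they averaged -0.27 (camera adjusted p = 0.0168, adjusted p = 0.573 with an estimated correlation), a call lost without 1 pool (adjusted p = 0.116 without Cpr-low pool 3 and 0.384 without liver-Cpr-null pool 2), with an average of -0.13 without liver-Cpr-null pool 2. Of male-biased liver genes, which include Hsd3b5, 0 were higher and 6 were lower of 13 tested members (0 and 6 adjusted over the list alone), and they averaged -0.47 (camera adjusted p = 0.0242, adjusted p = 0.147 with an estimated correlation), a call lost without Cpr-low pool 3 (adjusted p = 0.0903). Their median was -0.14, so the average owes much to a few members such as Hsd3b5. Of control genes, 4 were higher and 0 were lower of 12 tested members (6 and 1 adjusted over the list alone), and they averaged 0.12 (camera adjusted p = 0.0103, adjusted p = 0.112 with an estimated correlation) and 0.11 (camera adjusted p = 0.0163) within the second date. Within the second hybridization date, 3 liver-Cpr-null against 2 Cpr-low arrays, the averages were 0.57 (camera adjusted p = 1.58e-13) for Kupffer cell markers, 0.52 (camera adjusted p = 3.10e-13) for CAR and PXR targets and 0.19 (camera adjusted p = 7.48e-04) for fatty acid oxidation. They were -0.23 (camera adjusted p = 0.0324) for cholesterol biosynthesis and -0.45 (camera adjusted p = 0.0162) for male-biased genes, and the fit with the date as a block gives the same averages. Of 48 lists 22 were shifted between the models, and 0 with an estimated correlation in camera (11 at an unadjusted p under 0.05). Regrouping the liver-Cpr-null and Cpr-low arrays without regard to model still shifted up to 19 lists at the preset correlation. The fry test, which asks whether the genes of a list move one way and does not compare them with other genes, called 25, 17 and 20 lists in the 3 comparisons, in the order given here. Within the second date 468 genes differed, 416 of the 748 keeping their call, and with the date as a block 514 genes differed. The count was 460 without Cpr-low pool 2, 398 without liver-Cpr-null pool 1 and 403 without liver-Cpr-null pool 2, and the count of lists 14 without Cpr-low pool 3. With median scaling 527 genes were higher and 133 lower, and with the deposited scaling 521 and 179.

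Over the 3 models 1070 genes differed by the moderated F test. Against Cpr-lox, 198 genes were called in both models in the same direction, 86 rising and 112 falling, and 9 in opposite directions. Cyp2b10, Gstm3, Idi1, Rad51b and Ehhadh were among the 198. Independent lists of these sizes would share 7.50 rising and 10.6 falling genes and hold 18.4 in opposite directions, and 100 simulations of unchanged groups against shared controls gave at most 1 shared call. The simulation holds no real effects, so that value does not measure how far shared controls raise the 198. With 3 control pools the controls were not split, so part of the excess may come from them. Only the Cpr-lox arrays had the first scan date, and the simulation holds no date effect. Effects of that date could therefore add to the shared calls, and to the covariance given below. Across genes, which are not independent replicates, the fold changes correlated at 0.49 against a simulated 0.50, and 50.1% had the same sign against a simulated 66.7%. The median log2 fold change of all genes was -0.040 in liver-Cpr-null and 0.043 in Cpr-low, and -0.003 in each with median scaling. Offsets of opposite sign can lower the share of equal signs, and the simulated groups had none. That share therefore does not show that the models disagree. The covariance is not changed by a constant offset. The covariance of the fold changes was 0.0243 against a simulated 0.00545, a difference of 0.0188. The shared count was 107 with the date as a block, 114 with median scaling, 105 without Cpr-lox pool 2, 116 without liver-Cpr-null pool 1 and 129 without liver-Cpr-null pool 3.

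**Figure D3:**
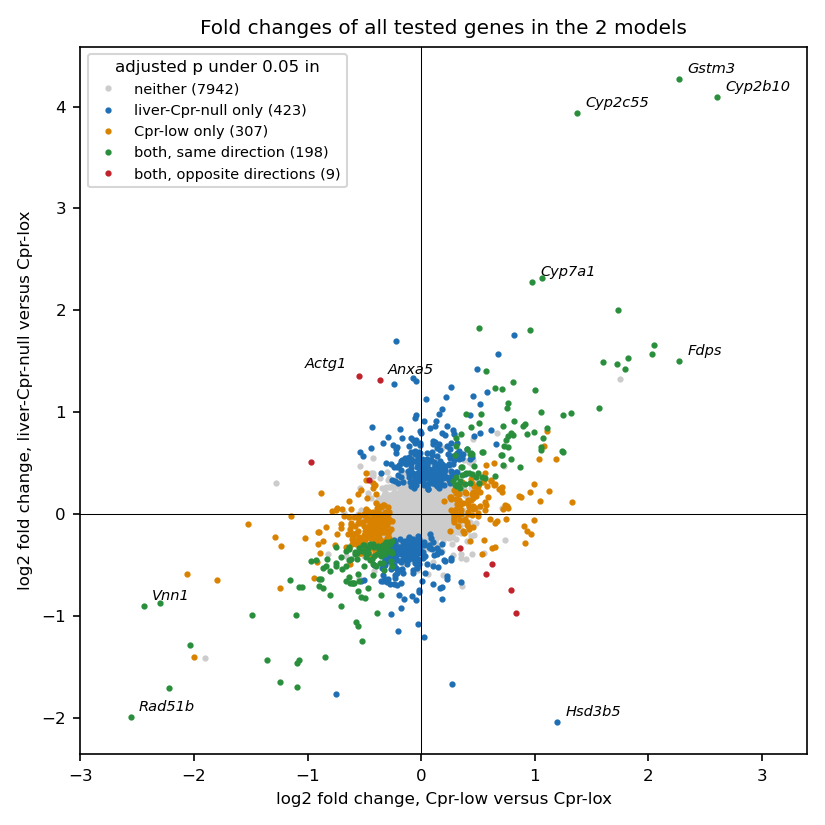
Log2 fold changes of all 8879 tested genes, Cpr-low against Cpr-lox on the horizontal axis and liver-Cpr-null against Cpr-lox on the vertical axis; dots are genes, coloured by where the adjusted p was under 0.05. The 198 genes called in both models in the same direction lie in the upper right and lower left quadrants, and 9 in the other quadrants.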

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

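The tests of dates and of cell share in this part were chosen after the results were seen, and the counts over other splits of the arrays before. In limma, 9 genes were called in opposite directions in liver-Cpr-null and Cpr-low, each against Cpr-lox, and the difference between the models passed the threshold for each. Independent lists would hold 18.4 such genes. With the log2 fold change in liver-Cpr-null first, they were Actg1 (1.35 and -0.55, difference 1.90), Tsc22d3 (-0.59 and 0.57, difference -1.16), Cyp2c39 (0.51 and -0.97, difference 1.48), Uox (-0.33 and 0.34, difference -0.68), Cela1 (-0.49 and 0.62, difference -1.12), Hsd3b2 (-0.98 and 0.83, difference -1.81), Anxa5 (1.31 and -0.37, difference 1.68), Ptpmt1 (0.33 and -0.46, difference 0.79) and Ppp1r3c (-0.75 and 0.79, difference -1.54). Uox, Ptpmt1 and Tsc22d3 lay outside the rule for named genes and were named after their values were seen. Cela1 is itself an exocrine pancreas marker, so the averages of that list are not independent of it. The list averaged -0.10 (camera adjusted p = 0.509) in liver-Cpr-null, 0.22 (camera adjusted p = 0.0322) in Cpr-low and -0.33 (camera adjusted p = 0.0404) between the models. Its medians were -0.06, 0.15 and -0.21, and 1 of 6 members was called in each comparison. When the date of hybridization was fitted as a block, the difference between the models kept its call for all 9, and both calls against Cpr-lox were kept for 1, Actg1, while the other 8 lost at least 1 of them. The kept probe set of Actg1 is of a type that may cross-hybridize, so Actg1 was absent when such types were left out. Leaving out 1 pool at a time ended a call against Cpr-lox for 8 of the 9 genes, Uox being the exception, under 1 or more of the omissions. The highest adjusted p for each was 0.140 for Actg1 in Cpr-low without Cpr-lox pool 2, 0.166 for Anxa5 in Cpr-low without Cpr-lox pool 2, 0.0553 for Tsc22d3 in Cpr-low without Cpr-lox pool 1, 0.161 for Hsd3b2 in Cpr-low without Cpr-low pool 1, 0.126 for Cyp2c39 in liver-Cpr-null without liver-Cpr-null pool 2, 0.0741 for Cela1 in liver-Cpr-null without liver-Cpr-null pool 2, 0.159 for Ptpmt1 in liver-Cpr-null without liver-Cpr-null pool 1 and 0.0702 for Ppp1r3c in Cpr-low without Cpr-lox pool 2. Hsd3b2 in Cpr-low had 0.49 (adjusted p = 0.0862) without Cpr-lox pool 2, and Cyp2c39 in liver-Cpr-null 0.80 ± 0.22 (adjusted p = 0.0924) with the date as a block. Of ribosomal protein genes, 0 rose and 0 fell of 36 tested members (0 and 0 adjusted over the list alone) in liver-Cpr-null and 0 rose and 3 fell of 36 tested members (1 and 6 adjusted over the list alone) in Cpr-low, with averages of 0.03 (camera adjusted p = 0.0178, adjusted p = 0.386 with an estimated correlation) and -0.10 (camera adjusted p = 4.07e-06, adjusted p = 0.225 with an estimated correlation). The first was 0.06 (camera adjusted p = 0.585) with the date as a block, and its call was lost without 1 pool (adjusted p = 0.0514 without liver-Cpr-null pool 2 and 0.0858 without liver-Cpr-null pool 3). That average was 0.054 without liver-Cpr-null pool 1, 0.021 without pool 3 and 0.021 without Cpr-lox pool 3. Between the models they differed by 0.13 (camera adjusted p = 9.18e-10, adjusted p = 0.126 with an estimated correlation), and 8 were higher and 0 were lower of 36 tested members (13 and 0 adjusted over the list alone). Of 1192 probe sets without a single gene name, 84 passed the threshold in liver-Cpr-null versus Cpr-lox, 67 in Cpr-low versus Cpr-lox and 122 between the models.

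The 630 genes that differed between liver-Cpr-null and Cpr-lox could reflect the hybridization date. With the date as a block 105 kept their call and 629 their sign, and the difference had a median of 1.03 times its size without the block while the median SE rose from 0.0853 to 0.134. Of the 525 calls that ended 285 had a smaller difference with the block, among them Hsd3b5 (-2.04 ± 0.36 to -0.80 ± 0.52), and their median ratio was 0.967. The blocked difference rests on 1 Cpr-low array of the first date that lay apart from the other Cpr-low pools on the first principal component (-17.1 against -7.42 and -3.92), which keeps this explanation open. The scan date and the control cannot be told apart. Of the 630 genes, 272 also differed from Cpr-low, scanned with liver-Cpr-null, in the same direction. Both comparisons use the same liver-Cpr-null pools, which favours such shared calls, and an expected count was not computed. The beta-actin 3' to 5' ratio also parted the liver-Cpr-null arrays (1.62 to 1.99) from all others (1.17 to 1.43), while the Gapdh ratio did not. The genotype stays open beside the hybridization and scan dates and RNA quality, which was not tested.

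Each comparison of 2 models has 10 splits of its 6 arrays, too few for a share under 0.05. The real split gave 630, 514 and 748 genes and the highest other 0, and for lists 31, 20 and 22 against 21, 19 and 19. Camera at its preset correlation thus shifted many lists under splits that called 0 genes. The other splits leave the models unequally mixed, so their counts are not a pure error rate. A count of shifted lists, above all the 20 in Cpr-low, therefore does not by itself show a model effect. The camera p-values at that setting may be too small. Over 100 splits of the 9 arrays 1, the real one, gave as many as 1070 genes by the F test (highest other 167). For shared genes 1, again the real one, gave as many as 198 (highest other 49). A random grouping of the arrays would therefore seldom give either count. The splits exchanged arrays across dates, while the dates part all liver-Cpr-null arrays from all Cpr-lox arrays. They therefore do not tell the model from the dates.

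The Kupffer cell markers differed between the models by 0.57, averaging 0.47 and -0.10 against Cpr-lox. A lower share of hepatocyte RNA would raise the markers of every other cell type alike, but the score of 13 Kupffer markers minus that of 45 markers of other types was higher in liver-Cpr-null than in Cpr-lox by 0.42 ± 0.08 (SE, 3 pools each), which argues against it as the whole cause. Against the 2 Cpr-low arrays of the same hybridization and scan dates the Kupffer score was higher by 0.56 ± 0.11, which argues against a date as the whole cause. Hepatocyte markers had a score difference from Cpr-lox of -0.14 ± 0.01. More macrophages, or more of these RNAs per macrophage, may account for the rise, and neither was tested.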

How the results depend on the processing

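Keeping the deposited scaling and fitting within a hybridization date were chosen after seeing the data, and all other alternatives before. Of 8 counts 1 stayed within 1.5 times its value under every alternative run, and 6 of 73 shifted lists and 61 of 99 fold changes of named genes kept direction and side of the threshold. Counting each gene under each alternative once, a call was lost in 113 cases and a sign changed in 2, and for lists in 195 and 3. With the hybridization date as a block, 22 of 48 named genes called in liver-Cpr-null versus Cpr-lox kept their call, 24 of 30 in Cpr-low versus Cpr-lox and 17 of 17 between the models. In that order of comparisons, the counts of 630, 514 and 748 genes became 210, 178 and 200 at 1.5-fold or more, and 296, 239 and 300 at an adjusted p under 0.01, as stricter thresholds must lower them. With the date as a block the first became 149 and the second 1090, and within the second date the third became 468. Leaving out 1 pool at a time gave 348 to 757, 274 to 494 and 398 to 796 genes, 726 to 1095 by the F test, 105 to 175 called in both models, and 24 to 33, 16 to 22 and 14 to 22 lists. The 198 genes called in both models became 114 with median scaling and 107 with the date as a block, and the shifted lists 4, 2 and 0 with an estimated correlation. With the date as a block camera's direction, which is relative to the other genes, turned from up to down for 3 lists in liver-Cpr-null versus Cpr-lox, none past the threshold there, with averages of -0.00357 for lipid droplet and lipid uptake, where the unblocked mean of 0.13 and median of -0.02 differ in sign, 0.0742 for the unfolded protein response and 0.0124 for oxidative phosphorylation. Alb, not past the threshold, turned to 0.0768 with quantile normalization and 0.0046 with the date as a block; except where stated, the cause was not tested. As for pairing, pools of the same number correlated at -0.210 to 0.465 in their deviations from the model means, 6 of 9 pairs over 0.1. Pairs of different numbers correlated at -0.429 to 0.263, 5 of 18 over 0.1. Of 9 arrays 2 correlated best with their own number. These values leave pairing open, and the numbers were not taken to pair the pools because the labels do not say that they do. With the replicate block 834, 673 and 1047 genes were called, 1366 by the F test and 277 in both models, with 31, 20 and 22 lists. Dim genes are limited by an unknown background step, and signal over background was not measured.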

Other observations

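The test of collection time in this part was chosen after the result was seen. Of proteasome subunits in Cpr-low, 0 rose and 14 fell of 39 tested members (1 and 22 adjusted over the list alone), with Psmc6 at -0.63 ± 0.10 and Psmd6 at -0.54 ± 0.08, and they averaged -0.25 (camera adjusted p = 6.66e-16, adjusted p = 0.150 with an estimated correlation). Other probe sets had -0.24 (adjusted p = 0.425) and -0.90 (adjusted p = 0.133). Within the first hybridization date, where 1 Cpr-low array stood against 3 Cpr-lox arrays, they averaged -0.29. Of genes of the endoplasmic reticulum and vesicle transport in liver-Cpr-null against Cpr-lox, 7 rose and 0 fell of 20 tested members (15 and 0 adjusted over the list alone), with Sec61b at 0.54 ± 0.09, and they averaged 0.26 (camera adjusted p = 3.39e-11, adjusted p = 0.0744 with an estimated correlation). Interferon-response genes there had a shift of 0.18 (camera adjusted p = 1.16e-04, adjusted p = 0.261 with an estimated correlation), and 4 rose and 0 fell of 16 tested members (6 and 0 adjusted over the list alone), among them Usp18 (0.70 ± 0.12). Of genes of antigen presentation, 5 rose and 0 fell of 13 tested members (5 and 0 adjusted over the list alone), with H2-Aa at 0.80 ± 0.18, and they averaged 0.22 (camera adjusted p = 7.22e-04, adjusted p = 0.343 with an estimated correlation). Of male-biased liver genes, 0 rose and 4 fell of 13 tested members (1 and 7 adjusted over the list alone), and they averaged -0.43 (camera adjusted p = 0.00546, adjusted p = 0.0744 with an estimated correlation), with a median of -0.21. Of female-biased liver genes, 0 rose and 2 fell of 6 tested members (0 and 2 adjusted over the list alone), and they averaged -0.51 (camera adjusted p = 0.0280, adjusted p = 0.138 with an estimated correlation), a call lost without Cpr-lox pool 2 (adjusted p = 0.0503). With the hybridization date as a block the averages were 0.20 (camera adjusted p = 0.0411) for endoplasmic reticulum and vesicle transport, 0.37 (camera adjusted p = 1.03e-04) for interferon response, 0.41 (camera adjusted p = 6.70e-04) for antigen presentation, -0.37 (camera adjusted p = 0.00376) for male-biased and -0.80 (camera adjusted p = 0.00605) for female-biased genes, and the calls were lost for Sec61b (0.36, adjusted p = 0.216), Usp18 (0.92, adjusted p = 0.0592) and H2-Aa (1.04, adjusted p = 0.137). The H2-Aa call was also lost without 1 pool (adjusted p = 0.0680 without Cpr-lox pool 2, 0.0685 without liver-Cpr-null pool 1 and 0.0541 without liver-Cpr-null pool 2). Female-biased genes averaged -0.78 in Cpr-low (camera adjusted p = 0.0115, adjusted p = 0.127 with an estimated correlation), with 3 of 6 falling. Their difference between the models, 0.27 (camera adjusted p = 0.569), did not pass, so their fall was not particular to liver-Cpr-null. The list shares Cyp4a14 and Acot3 with the list of fatty acid oxidation and PPAR-alpha targets. Of acute phase genes in Cpr-low, 2 rose and 5 fell of 23 tested members (2 and 7 adjusted over the list alone), and they averaged -0.36 (camera adjusted p = 8.54e-04, adjusted p = 0.387 with an estimated correlation), against -0.38 within the first date and -0.18 (camera adjusted p = 0.150) without Cpr-lox pool 3. In liver-Cpr-null 1 rose and 5 fell, averaging -0.22 (camera adjusted p = 0.00883, adjusted p = 0.383 with an estimated correlation). Without Cpr-lox pool 3 that average was -0.03 (camera adjusted p = 0.883). The difference between the models, 0.15 (camera adjusted p = 0.569), did not pass. The fall was thus not particular to Cpr-low, and in both models its call rested on 1 control pool.

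Of clock genes in liver-Cpr-null against Cpr-lox, 0 rose and 4 fell of 12 tested members (0 and 6 adjusted over the list alone), with Dbp at -1.76 ± 0.45 and Tef at -0.55 ± 0.10, and they averaged -0.36 (camera adjusted p = 6.05e-04, adjusted p = 0.0906 with an estimated correlation). With the hybridization date as a block they averaged -0.30 (camera adjusted p = 0.00326), and the calls were lost for Dbp (-1.01, adjusted p = 0.536) and Tef (-0.43, adjusted p = 0.194). The Dbp call was also lost without 1 pool (adjusted p = 0.0916 without Cpr-lox pool 1, 0.109 without Cpr-lox pool 3, 0.122 without liver-Cpr-null pool 2 and 0.112 without liver-Cpr-null pool 3), and other probe sets had -0.68 (adjusted p = 0.0793) for Dbp and 0.03 (adjusted p = 0.921) for Tef. Against Cpr-low, 0 were higher and 3 were lower of 12 tested members (0 and 3 adjusted over the list alone), and they averaged -0.32 (camera adjusted p = 0.00866, adjusted p = 0.215 with an estimated correlation), a call lost without Cpr-low pool 3 (adjusted p = 0.0569), and -0.30 (camera adjusted p = 0.00240) within the second date. A different time of day of liver collection is a candidate explanation, since collection times are not given in the sources used here. It would raise the genes that peak opposite to Dbp. The mean log2 change of 5 of them, Arntl, Clock, Npas2, Nfil3 and Cry1, which lie outside the rule for named genes and were chosen after the clock result was seen, was -0.031 ± 0.040 (SE over genes). The filter on dim probe sets was dropped for this test. Arntl, Npas2 and Cry1 had mean signals of only 123, 80.6 and 36.1, and changes of such dim genes are understated. The test could therefore miss a rise, which leaves this open.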
